A study of Sorghum bicolor with 2 samples.

How the data were processed

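Leaf RNA of 1 control and 1 drought-treated group of sorghum plants was measured by degradome sequencing. Per the labels' protocols, polyadenylated RNA was ligated to a 5′ adapter with an MmeI site, copied to cDNA, amplified for 5 cycles, cut with MmeI, joined to another adapter and amplified for 10 more cycles. Per the file headers, the deposited values are counts of reads for each different tag of 20 bases. They are whole numbers and not normalized. Adapter trimming, aligner and genome build are not given in the sources used here. The header line occurred 14 times in the control table and 19 times in the drought table and was removed, and each tag was listed once. Groups follow the treatment label, and with 1 library per group nothing was averaged or tested between conditions.

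Many of the most abundant tags were adapter sequence. A tag was left out when it held any 8 bases in a row of 4 common Illumina adapter sequences, ended in the first 5 to 7 bases of the small RNA 3′ adapter, or began or ended with 12 A. The labels name no adapter sequence, and these were chosen after seeing the data. The remaining 1585769 control and 2458122 drought reads were the scale of all ratios. A count of 0 allows 1.89 reads per 1000000 in control and 1.22 in drought. Tags read once made up 49.9% of the remaining control reads and 48.1% of the drought reads. Copies from PCR are not independent molecules, so intervals and floors cover counting error only.

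For each tag or family the ratio of drought to control carries the exact interval of a ratio of 2 Poisson counts, from the Clopper-Pearson interval of the drought share. At least 20 reads over both libraries were required. Named tags follow a rule set before the data were examined for the case of no reference: the 10 with the highest and the 10 with the lowest interval bound among tags with at least 100 reads. The most abundant tags, the miR160 tags and the histone H4 tag were named in addition, after their values were seen.

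The plan had been to match tags to transcripts. The reference used here was a table of gene names without sequences, so gene totals, gene list medians, target scores, transcript regions and exon junctions were not analysed here, and the following replaced them. Each tag was translated in 3 frames and matched to 6 consecutive residues of 40 conserved protein families, written from general knowledge of plant proteins. The first 30 families were written after the most drought-enriched tags had been seen. The last 10, from NADP malic enzyme to Cu/Zn superoxide dismutase, were added after the ratios of the first 30 and before their own counts. Reversed peptides served as background, with 4.29% of the matched number in control and 6.12% in drought. Of the 21 gene lists fixed before the data were examined, 18 had a family. Osmolyte synthesis, cuticle and sugar transport had none and were not analysed here. A family can include proteins outside its name, and related genes are not told apart.

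For 30 small RNAs, written from general knowledge before the data were examined, reads beginning with the complement of bases 1 to 10 were counted. A small RNA was counted when the lower Poisson bound exceeded the highest count at tag offsets 1 to 9, beside 100 dinucleotide-shuffled sets. Methods were tested on simulated data. All 3000 planted peptide tags and all 10 planted small RNAs were recovered, and 1 small RNA passed in random tags with none planted. The planted tags were made from the same peptides and exact complements that were searched for. Their recovery checks the code alone, not how well real sorghum transcripts are found. Recovery of changed tags was low at small folds, with 19.5% of tags planted at 3-fold.

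Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for alternative scaling factors alone. Alternatives covered scaling, minimum counts, fold, copy number, adapter words, peptide background, miRNA pairing and depth.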

Results

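Degradome libraries record the 5′ ends of uncapped, polyadenylated RNA, the ends left when a transcript is cleaved or decays. Each RNA 5′ end is read as a tag of 20 bases. The series held 1 library from leaves of control sorghum (Sorghum bicolor) and 1 from leaves of plants from which water was withheld for a week, starting 73 days after sowing. Both were grown at 28°C by day and 20°C by night with 14 h of light. Heat and combined stress were not analysed here. The control library held 18871183 reads of 1335068 different tags and the drought library 21461010 reads of 1862421 different tags. Reads carrying adapter sequence or poly(A) made up 91.6% of the control library (95% Clopper-Pearson interval 91.58% to 91.61%) and 88.5% of the drought library (88.53% to 88.56%). The 1585769 control and 2458122 drought reads that remained covered 901726 and 1409967 different tags, and 178658 tags occurred in both libraries. At the same number of reads as the control, the drought library held 970426 different tags.

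With 1 library per group, each difference below has no replicate check and compares 2 libraries, not the conditions, so no p-value is given. Intervals are exact 95% intervals for counting error only. A difference was counted when the whole interval of the drought over control ratio, in reads per 1000000 remaining reads (RPM), lay above 2 or below 0.5. No transcript sequences were used here, so tags are named by sequence. Gene groups are given as tags able to encode 6 consecutive residues of a conserved protein, which is not an assignment to a gene.

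The most abundant remaining tag in both libraries, TCTCATGGAGAGTTCGATCC, made up 10.4% of the control reads and 5.70% of the drought reads. The next, GGCGGATGTAGCCAAGTGGA, stood at 2.87% and 2.58%. TCAAAAGAGGAAAGGCTTGC followed with 1.76% and 1.05%, TACCTGGTTGATCCTGCCAG with 1.28% and 0.539%, and GGAGAGATGGCTGAGTGGAC with 0.881% and 0.942%. GCGACCCCAGGTCAGTCGGG fell from 9418 to 2841 RPM, a ratio of 0.302 (0.293 to 0.310). The 10 most abundant tags together took 18.8% of the control reads and 11.4% of the drought reads. They were not assigned to any RNA, so their shares are not a measure of messenger RNA decay. They are part of the main scale, and scaling without them is given below. That scaling still holds tags that overlap them with shifted starts. An example is a tag with 298 control and 216 drought reads that overlaps the most abundant tag. Leaving out the 10 tags may therefore not remove all reads of the same RNAs.

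The comparison of drought with control leaves asks which transcripts gave more or fewer uncapped ends. Transcript levels were not measured here, so a change in the amount of a transcript cannot be told apart from a change in its decay. Tags able to encode dehydrins, proteins that accumulate in dehydrating plant tissue, rose from 36 control reads to 6225 drought reads, a ratio of 112 (80.5 to 159). Tags matching class I small heat shock proteins, chaperones that hold unfolding proteins, rose from 24 to 713 reads, a ratio of 19.2 (12.8 to 30.1). Tags matching protein phosphatase 2C, the enzyme class that includes negative regulators of abscisic acid signalling, rose from 4 to 44 reads, a ratio of 7.10 (2.58 to 27.2), although reversed peptides of this family had 5 control and 8 drought reads, no fewer than its own 4 in control. In the other direction, tags matching fructose-bisphosphate aldolase, the Rubisco small subunit, pyruvate phosphate dikinase, PEP carboxylase and the LHCB antenna proteins fell. Of 40 protein families, 34 had at least 20 reads, of which 3 were higher and 5 lower in drought.

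The dehydrin reads were spread over 633 different tags, and the most abundant held 3.02% of them. The motif KIKEKLPG, the conserved segment of dehydrins and the only part of this group fixed before the data were examined, had 0 control reads and 111 drought reads, at least 23.9-fold higher on a floor of 3 counts, with an exact lower bound of 19.1. The other dehydrin peptides were written after the most drought-enriched tags had been seen, so their ratio is not independent evidence. Reversed dehydrin peptides, the background for random matches, had 22 control and 41 drought reads. Reversed small heat shock peptides rose from 10 control to 156 drought reads, so this background was itself strongly higher in drought and is not random matching alone. With these reads subtracted, the ratio of the small heat shock family was 25.7 (15.2 to 47.3), which passed. Because that background differed between the libraries, the subtraction does not test whether the matches are specific. Intervals after subtraction of reversed matches, here and below, treat the differences as plain counts.

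Among the other chaperones, cytosolic HSP70 stood at 225 control and 589 drought reads, a ratio of 1.69 (1.45 to 1.98), and HSP90 at 1.18 (0.790 to 1.78). Neither passed. The HSP70 motif FDLGGGTFDVS, fixed before the data were examined, gave 25 and 48 reads and a ratio of 1.24 (0.749 to 2.10). SnRK2 kinases, the positive arm of abscisic acid signalling, gave 11 and 24 reads, a ratio of 1.41 (0.664 to 3.18). PIP aquaporins, the plasma membrane water channels, gave 1.18 (1.03 to 1.36) and ubiquitin 1.13 (1.06 to 1.21). Of 3 antioxidant families none passed: catalase was at 1.29 (0.714 to 2.41), Cu/Zn superoxide dismutase at 1.27 (0.919 to 1.77) and ascorbate peroxidase at 0.771 (0.512 to 1.17). Of the stress transcription factor families, R2R3 MYB alone had enough reads, with a ratio of 1.10 (0.613 to 2.01). NAC, AP2/ERF and WRKY domains had 6, 4 and 10 reads over both libraries, too few for a difference to be detectable at this depth.

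**Figure D1:**
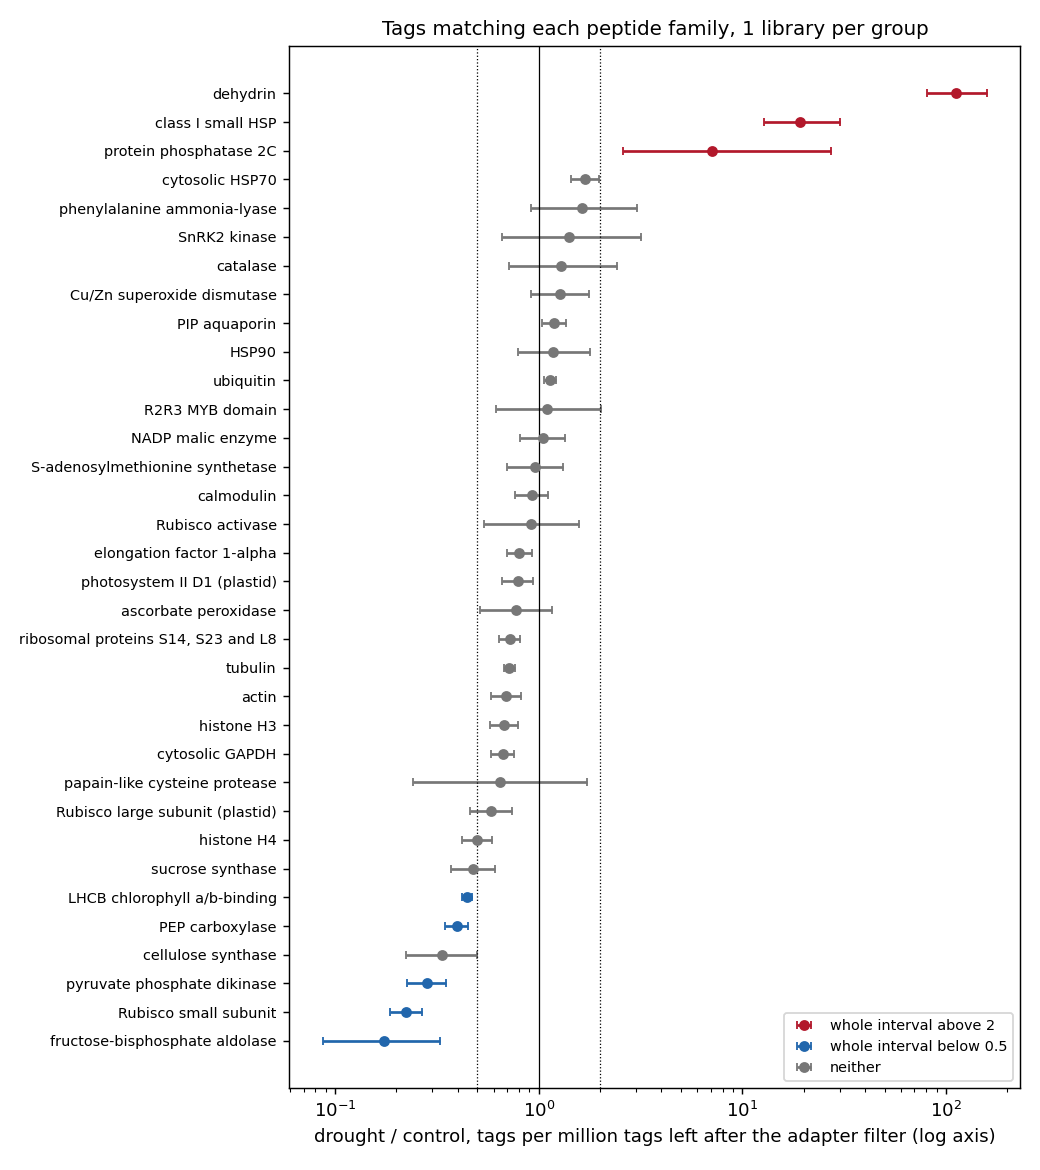
Ratio of drought to control RPM, scaled to the remaining reads (log axis) for the 34 peptide families with at least 20 reads, 1 library per group. Points are ratios, bars exact 95% counting intervals, dotted lines mark 0.5 and 2; dehydrin lies at 112 and fructose-bisphosphate aldolase at 0.175.

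Photosynthesis families made up the lower group. In the Calvin cycle, 2 of 4 families fell: fructose-bisphosphate aldolase from 48 to 13 reads, a ratio of 0.175 (0.0868 to 0.328), and the Rubisco small subunit from 478 to 166 reads, a ratio of 0.224 (0.187 to 0.268). The plastid-encoded Rubisco large subunit was at 0.583 (0.460 to 0.737). Its reversed peptides had 30 control and 82 drought reads, and with these subtracted it passed as lower at 0.299 (0.215 to 0.412). Rubisco activase was at 0.918 (0.541 to 1.58). Both C4 mesophyll families fell: pyruvate phosphate dikinase, which regenerates the carbon acceptor phosphoenolpyruvate, with a ratio of 0.281 (0.226 to 0.349) and PEP carboxylase, which fixes carbon before it passes to the bundle sheath, with 0.396 (0.348 to 0.451). NADP malic enzyme, which releases that carbon in the bundle sheath, had 102 and 165 reads, a ratio of 1.04 (0.810 to 1.35). LHCB antenna proteins fell from 2647 to 1826 reads, a ratio of 0.445 (0.419 to 0.473), and photosystem II D1 was at 0.788 (0.659 to 0.941).

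Actin, tubulin, elongation factor 1-alpha and cytosolic GAPDH, housekeeping genes of the cytoskeleton, translation and glycolysis, together stood at 0.717 (0.682 to 0.753). Calmodulin at 0.922 and S-adenosylmethionine synthetase at 0.958, also on the housekeeping list, were not part of this scale. Of the pooled reads of the 4 families, tubulin gave 1888 of 2979 in control and 2100 of 3310 in drought. Relative to these 4 families, the ratio was 156 (112 to 222) for dehydrin, 26.7 (17.8 to 42.0) for small heat shock proteins, 0.244 (0.121 to 0.457) for aldolase, 0.313 (0.260 to 0.374) for the Rubisco small subunit and 0.393 (0.315 to 0.487) for pyruvate phosphate dikinase. On that scale LHCB was at 0.621 (0.585 to 0.659) and PEP carboxylase at 0.553 (0.485 to 0.629), and neither passed, while HSP70 passed at 2.36 (2.02 to 2.76). These relative intervals treat the housekeeping counts as exact and are therefore too narrow. The HSP70 lower bound lies so near 2 that its call on that scale is not secure. With each different tag counted once, dehydrin at 11.5 (8.12 to 16.7) and small heat shock proteins at 6.90 still passed. Pyruvate phosphate dikinase at 0.395 (0.279 to 0.553), PEP carboxylase at 0.499 (0.418 to 0.595) and protein phosphatase 2C at 4.96 (1.75 to 19.3) then did not. Scaling by all reads of each library also ended the calls of LHCB (0.607) and PEP carboxylase (0.540).

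Growth and cell wall families did not pass under the main settings. Cellulose synthase was at 0.335 (0.222 to 0.5004) and passed as lower under TMM factors (0.327), DESeq2 factors (0.320), scaling without the 10 most abundant tags (0.308), its most abundant tag left out (0.314) and reversed matches subtracted (0.186, 0.105 to 0.313). Histone H4 was at 0.496 (0.419 to 0.587) and passed as lower with reversed matches subtracted (0.356, 0.292 to 0.433). Sucrose synthase was at 0.477 (0.372 to 0.610) and histone H3 at 0.675 (0.578 to 0.788). Of the histone H4 reads, 29.6% came from 1 tag, TGGGGCGTGGCAAAGGTGGA. Ribosomal proteins S14, S23 and L8 together were at 0.720 (0.639 to 0.812), phenylalanine ammonia-lyase, the entry enzyme of lignin synthesis, at 1.63 (0.911 to 3.05) with 17 control and 43 drought reads against 21 and 30 for its reversed peptides, calmodulin at 0.922 (0.766 to 1.11), S-adenosylmethionine synthetase at 0.958 (0.698 to 1.32) and papain-like cysteine proteases at 0.645 (0.241 to 1.73). Phosphoribulokinase, expansin and argonaute had 13, 11 and 9 reads over both libraries. Set beside 10000 random tag sets of the same size and read counts, dehydrin, small heat shock proteins, protein phosphatase 2C and HSP70 lay at percentile 100. These families were written after the most drought-enriched tags had been seen, so their percentiles are not independent evidence. Percentile 0 was not particular to the families called lower. It held aldolase, the Rubisco small subunit, PEP carboxylase and pyruvate phosphate dikinase, and also the Rubisco large subunit, actin, tubulin, cytosolic GAPDH, the ribosomal proteins, histone H3, sucrose synthase and cellulose synthase. D1 lay at 0.02, elongation factor 1-alpha at 0.06 and LHCB at 0.18.

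Tags were also compared singly, whether or not they matched a family. Of 8654 tags with at least 20 reads, 1224 were higher in drought and 332 lower, so 78.7% of the calls were higher. Scaling by all reads of each library moved that share to 93.8% and scaling by the housekeeping families to 94.3%, with median shifts of 0.45 and 0.48 on the log2 scale. It was 75.7% with DESeq2 factors, 71.9% without the 10 most abundant tags in the scaling and 68.1% at a minimum of 100 reads, where the median log2 ratio was -0.19. Joined by overlaps of at least 15 bases, the higher tags formed 345 stretches and the lower tags 211. Of the 1224 higher tags, 92 matched a family, 86 of them dehydrin and 6 small heat shock peptides. The dehydrin peptides other than KIKEKLPG and the small heat shock peptides were written after the most drought-enriched tags had been seen. These counts are therefore not independent evidence. In simulated libraries of 8654 tags, 31.5% of tags planted at 4-fold and 78.0% of those planted at 8-fold were recovered, and 3 tags were called with no change planted. These simulated libraries held Poisson counting error alone. The 3 calls are therefore no false-call rate for PCR copies, library preparation or plants.

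Among the 10 tags with the highest lower bounds, 5 encode dehydrin peptides. The matched peptides lie outside KIKEKLPG and were written after the most drought-enriched tags had been seen, so this count is not independent evidence. TGAGGACGACGGCATGGGCG had 0 control and 189 drought reads, at least 40.6-fold higher on that floor, with an exact lower bound of 32.7. GTTCCAGCCAGCGAGGGAGG followed with 0 and 147 (at least 31.6-fold, exact lower bound 25.4), and TCGTCTGAGGACGACGGCAT, GTCTGAGGACGACGGCATGG and CTCGTCTGAGGACGACGGCA, which overlap the first, had 0 control and 141, 123 and 122 drought reads. The other 5 matched no family. CTGTGGTTTTGTTCAACCAA had 1 control and 237 drought reads, a ratio of 153 (27.2 to 6064), and its neighbour TGTGGTTTTGTTCAACCAAG 0 and 139. ATGCACGGGGACAGTTTATA had 0 and 130, AAGAACAGAAGAGAGACGAG 0 and 128, and TTGTTTCAAGGTGGATCGCG 1 and 181 reads, the last a ratio of 117 (20.7 to 4637).

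The 10 tags with the lowest upper bounds matched no family. The last one listed here overlaps, in all bases but its first, the abundant tag given above with a ratio of 0.302. Its fall is therefore not an independent observation. The overlapping pair TGTGGCGGCATGGGGATGTC and GTGGCGGCATGGGGATGTCA fell to ratios of 0.0764 (0.0544 to 0.105) and 0.0943 (0.0652 to 0.133), from 363 and 260 control reads. A further overlapping pair, ATCACACACACATACACAAC and CATCACACACACATACACAA, fell to 0.105 (0.0661 to 0.162) and 0.133 (0.0914 to 0.190). GTCGAACGGGAAGTGGTGTT fell to 0.154, TCGTTCAACTGGACTGGCTT to 0.178, AAGGAAGCTATAAGTAATGC to 0.179, GGGAGTATTATAAAAAGAGG to 0.181, CTGAAGGGCCGTCGAAGACT to 0.210 and AGCGACCCCAGGTCAGTCGG to 0.251 (0.207 to 0.303).

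Degradome libraries are made to find miRNA-guided cuts, which fall between bases 10 and 11 of the miRNA, so that the tag begins with the complement of miRNA bases 1 to 10. That signature was clear for miR160, a regulator of auxin response factors. Its complement GAGCCAGGCA opened 77 control and 83 drought reads, and no other position in the tag held more than 5 in control or 4 in drought. GAGCCAGGCATGCTCAATTT had 52 control and 49 drought reads, a ratio of 0.608 (0.403 to 0.916), and GAGCCAGGCATGCGCAATTC 16 and 28, a ratio of 1.13 (0.590 to 2.23). The pooled miR160 ratio was 0.695 (0.504 to 0.961), which did not pass, and it was 0.970 relative to the housekeeping families.

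**Figure D2:**
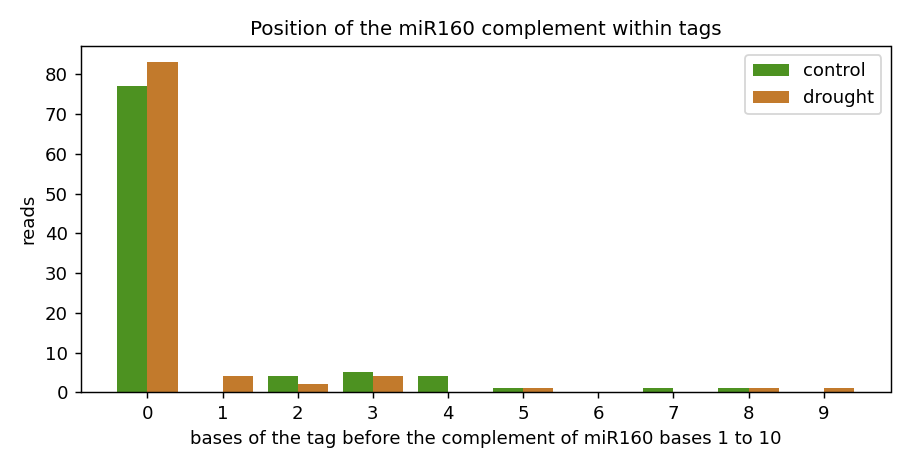
Reads holding the complement of miR160 bases 1 to 10 by the number of tag bases before it, in 1 control and 1 drought library. Bars start at 0; at position 0 they reach 77 and 83 reads, and at later positions at most 5 and 4.

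Of 30 small RNAs tested, 2 exceeded the other positions in each library: miR160 in both, miR171 in control with 9 reads and miR394 in drought with 9 reads. Dinucleotide-shuffled small RNAs gave a mean of 0.28 ± 0.552 (SD of 100 sets) in control and 0.47 ± 0.731 in drought, and 5 and 9 of the 100 sets gave at least 2. miR160 passed in both libraries under all alternatives run, and the others depended on the setting. miR394 passed under the main setting alone. In drought miR156 and miR164 passed with 10-base adapter words, miR397 with 1 base to either side allowed and miR169 with the first base unpaired. In control miR171 was kept with 10-base adapter words and gave way to miR159 with 1 base to either side allowed. With a minimum of 10 reads miR160 alone passed in either library. miR319 could not be measured, since its complement shares a word with an adapter. For miR156 the site counts were 4 and 13 reads, for miR164 5 and 11, and for miR393 5 and 2.

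The 3 reading frames held similar shares. The lowest was frame 1 with copies counted and frame 0 with each different tag counted once, in both libraries. With copies counted, in control 34.0% (33.1% to 34.9%), 30.7% (29.8% to 31.5%) and 35.3% (34.5% to 36.2%) of 11558 peptide matches began at tag base offsets 0, 1 and 2, and in drought 33.8% (33.2% to 34.5%), 32.3% (31.6% to 32.9%) and 33.9% (33.2% to 34.6%) of 19317. A ribosome halted on a stop codon would place a stop triplet at offsets 16 and 17 of the tag. The mean share per offset with a stop triplet there was 3.30% of control and 3.82% of drought reads. At offsets 10 to 15 the means were 3.63% and 4.06%, ratios of 0.907 and 0.942. Offset 11 raised these means, with 4.69% in control and 5.03% in drought. The lowest of offsets 10 to 15 held 3.34% in control and 3.81% in drought, so the drought mean lay within their range. With each different tag counted once, the means at offsets 16 and 17 lay below that range in both libraries.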

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

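The tests in this part were chosen after the results were seen, except that counting each different tag once for the dehydrin ratio and the motif KIKEKLPG were set before the data were examined. Reads with words of the TruSeq index adapter alone, which no comparison used, numbered 21883 in the drought library (0.102% of all reads) and 8497 in control (0.0450%). The tag GAAGAGCACACGTCTGAACT accounted for 5039 of them in drought and 6 in control.

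Dehydrin-matching tags were higher in the drought library. A few over-amplified tags could raise reads without more RNA ends, but with each different tag counted once the ratio was still 11.5 (8.12 to 16.7). Choice of peptides after the tags were seen is argued against by KIKEKLPG alone, at least 23.9-fold higher on a floor of 3 counts, with an exact lower bound of 19.1. A difference between the sampled plants or library preparations other than drought cannot be told apart from drought, since each group had 1 library.

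Photosynthesis-matching tags of the antenna, Calvin cycle and C4 mesophyll lists, pooled over 8 families, were at 0.427 (0.407 to 0.447). A general scaling shift could lower them. Relative to the housekeeping families, with their counts treated as exact, the pooled ratio was 0.595 (0.568 to 0.624). A shift is therefore not the whole cause for the pool, of which LHCB gave 2647 of 4489 control reads. On that scale D1 at 1.10 (0.920 to 1.31), Rubisco activase at 1.28 (0.755 to 2.20) and the Rubisco large subunit at 0.813 (0.642 to 1.03) had intervals that include 1, so a shift stays open for these families, and NADP malic enzyme, outside the pool, was at 1.46 (1.13 to 1.88). With each different tag counted once the pooled relative ratio was 0.751 (0.698 to 0.808), so a few over-amplified tags are not the whole cause either. LHCB and PEP carboxylase passed at 0.445 (0.419 to 0.473) and 0.396 (0.348 to 0.451) and not relative to housekeeping, at 0.621 (0.585 to 0.659) and 0.553 (0.485 to 0.629), because the shift moved their intervals across 0.5, and drought and other differences between the plants stay open.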

How the results depend on the processing

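No paired analysis was possible because each group had 1 library. Adapter words of 10 bases, scaling without the 10 most abundant tags or by housekeeping families, subtraction of reversed matches, each family's most abundant tag left out, frames without dehydrin, an unpaired first miRNA base and 4-fold for families were chosen after seeing the data. No called family changed direction under any alternative run for it. Named tags were rerun under other scalings alone, and none changed direction. A scaling multiplies all ratios by a common factor, too small here to reverse any of these tags or families. For the scalings this outcome was therefore fixed in advance. Dehydrin ranged from 11.5 to 285 and the Rubisco small subunit from 0.205 to 0.335. Lower tags numbered 110 with all-read scaling, 102 with housekeeping scaling and 694 with no minimum. A minimum of 100 left 184 higher and 86 lower, and 4-fold left 464 and 39. Lower families numbered 3 with all-read scaling, 3 with housekeeping scaling, 3 with each tag counted once, 8 with reversed matches subtracted and 0 at 4-fold. LHCB lost its call with 10-base adapter words (0.474, 0.447 to 0.504), protein phosphatase 2C and aldolase theirs with a minimum of 100, and at 4-fold dehydrin and small heat shock proteins alone passed. Calls lost or gained under other settings stand beside the ratios in the results. Small RNAs above background fell to 1 in each library with a minimum of 10, to 1 in control with the first base unpaired and to 1 in drought thinned to the control's number of remaining reads, and rose to 3 in drought with 10-base adapter words. The miR160 ratio was 0.970 with housekeeping scaling. With each tag counted once, frame shares were 30.9%, 32.9% and 36.3% in control and 30.5%, 33.4% and 36.1% in drought, and stop triplet ratios 0.940 and 0.963. With families weighted equally, frames 0 and 1 in control were 34.9% and 29.8%, and frames 0 and 2 in drought 30.7% and 37.1%. Adapter shares were 88.6% and 85.5% with 10-base words and without the rule on tag ends. The causes were not tested. Splitting tags among genes, mismatches, target scores, site categories and ratios within a transcript were not run, since no transcript sequences were used. Depth limits families with few reads, such as NAC with 6.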

Other observations

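The tests in this part were chosen after the results were seen. Some tags began with the first bases of mature miRNAs. Reads beginning with the first 12 bases of miR528, a monocot miRNA, numbered 5759 in control and 5950 in drought before the adapter filter. The first 18 bases were present in 2189 and 1958 of them. For miR156 they numbered 903 and 842, with the first 18 bases in 134 and 100 of them. The 12-base counts were 88 and 69 for miR529 and 72 and 88 for miR164.

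Random decay of the precursor would spread the starts, yet 97.2% (96.9% to 97.5%) of reads with the first 12 bases of miR528 began exactly at them. Of these 11709 reads, 59.6% (58.8% to 60.5%) ran into the start of the small RNA 3′ adapter after 12 to 17 bases, against 6.56% of other reads with no adapter word in their first 12 bases, both shares taken before the adapter filter. They may be short RNA pieces joined directly to that adapter, not ends of polyadenylated transcripts. No explanation that involves the drought treatment was tested.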
